A study of Hebeloma cylindrosporum with 4 samples.

How the data were processed

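RNA of the ectomycorrhizal fungus Hebeloma cylindrosporum was measured by RNA sequencing in 4 libraries, 2 from free-living mycelium and 2 from ectomycorrhizas, the root tips that the fungus forms together with a tree host. The mycelium was a 6-day-old pure culture of the wild-type strain TV98 IV3 on a nutrient agar with 0.5 g per litre of fructose, lifted from a cellophane sheet. The ectomycorrhizas came from maritime pine (Pinus pinaster), inoculated as 20-day-old seedlings and grown in a greenhouse in a sterilized peat soil with 80% organic matter. Reads were 100 bp Illumina reads, per the series design text. RNA was extracted with a plant RNA kit and purified on a second column, and libraries were made by a sequencing service, per the labels' protocols. The series text calls the 2 libraries of each group biological replicates, but nothing names their plants, pots or cultures. The p-values therefore rest on the spread between these libraries only, with a dispersion shared by both groups and shrunk across gene models.

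Each library came with 1 table of 15382 gene models of the Hebcy2 annotation of the Joint Genome Institute, identified by numeric protein ID, with transcript length. The authors deposited 2 raw read counts per gene model, per the file headers: the total gene reads, and the unique gene reads, which leave out reads that also match another model. The authors also deposited RPKM values, per the file headers; each equals total gene reads divided by transcript length and by the library's own sum of total gene reads, with differences of at most 5e-06. RPKM therefore carries a scaling by total reads only. The aligner, the counting tool and their settings are not given in the sources used here, nor is how pine reads were removed; RNA of both partners is present in an ectomycorrhiza, so a pine read that resembled a fungal transcript would be counted with it. Strand use in counting is not given either, so reads of overlapping and antisense models cannot be separated.

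The tables pair no ID with a gene name or function, and no genome or annotation was used here, so gene models carry no coordinates, product or pathway. Of 28 functional gene lists defined by product text or protein sequence, 0 could be built. The rule for named genes, fixed with the design before the data were examined, ranked gene models by log2 fold change among those with an adjusted p under 0.05, non-overlapping groups and a mean of at least 10 normalised CPM in the higher group. Without product text that rule allowed the first 2 in each direction. Gene models were otherwise grouped by size of change, abundance and transcript length. The 5-fold limit and the share of reads in the 10 and 100 most abundant were fixed with the design. The 100-fold limit, the abundance deciles, the length classes and the gene models present in 1 group were chosen after the data were seen. So was the number of gene models holding 50% of the reads.

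Total gene reads were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group (11471 gene models kept), TMM scaling, and the quasi-likelihood test with robust shrinkage on all 4 libraries with group as the only term. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05; a second count required a change of at least 5-fold. Normalised CPM are CPM values computed on the TMM-scaled library size. A group with 0 reads in both libraries was set to 3 reads over the group, which is 0.058 normalised CPM in mycelium and 0.48 in ectomycorrhiza, and its folds are given as bounds. This floor and all binomial intervals cover counting error only, since the reads carry no molecular identifiers. With 2 libraries against 2, an exact two-sided permutation test cannot go below p = 0.333, so single values per library are given without a test.

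The fit was tested on simulated data: counts for the 11471 tested gene models at the real means and library sizes, with 200 models changed in each of 10 draws. With 1 dispersion trend for both groups, 92.2% of 5-fold changes and 16.7% of 2-fold changes were recovered, and 3.71% of calls were false. With a dispersion per gene the false share was 8.17%. With a separate trend for each group (median dispersion 0.0208 in mycelium and 0.114 in ectomycorrhiza), 70.0% of 5-fold changes and 2.60% of 2-fold changes were recovered, and 0.684% of calls were false. These shares hold only for the simulated setting, with 200 changed models. In the data 5944 models were called, so the shares recovered and false there are not known from these draws.

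Alternatives were RLE and upper-quartile scaling, total counts alone, DESeq2 1.42.0, limma-voom (limma 3.58.1), 2 other filters, unique gene reads, limma on log2(RPKM + 1), a replicate block and leaving out each library. Fold changes on the log2(RPKM + 1) scale understate the change of low gene models. Added after the data were seen were thinning all libraries to the shallowest total, thinning to 1 TMM-scaled size, taking a smooth trend on transcript length out of each library, a crossed pairing, RPKM for the number of gene models holding 50% of the reads, and deciles of abundance ranked by each group alone. Gene models with over 50% of their reads shared with another model (99, of which 55 were tested) were treated as uncertain, and no named gene model had a shared read. Figures were drawn with matplotlib 3.10.9.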

Results

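The data comprised fungal read counts for 15382 gene models in 2 libraries of free-living mycelium and 2 of ectomycorrhizas formed with Pinus pinaster. The mycelium libraries held 17774509 and 19341938 gene reads, and the ectomycorrhiza libraries 4748150 and 3967725, a 4.26-fold difference in mean depth. One read corresponded to 0.056 and 0.052 CPM in mycelium and to 0.21 and 0.25 CPM in ectomycorrhiza, so low transcripts were measured less precisely in the symbiotic tissue. In total, 1872 gene models had no read in any library. Reads shared between gene models made up 0.352% and 0.343% of the mycelium reads and 0.205% and 0.182% of the ectomycorrhiza reads.

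The fungal transcriptomes of the 2 tissues were far apart. Across the 13510 gene models with a read, log2(CPM + 1) values correlated with Pearson's r = 0.992 (Spearman's rho = 0.991) between the mycelium libraries and r = 0.973 (rho = 0.969) between the ectomycorrhiza libraries. Between the groups r ranged from 0.809 to 0.823 and rho from 0.828 to 0.843. These correlations are across genes, which are not independent replicates. The first principal component of the tested gene models carried 88.8% of the variance and separated mycelium from ectomycorrhiza, and the second, with 9.84%, separated mainly the 2 ectomycorrhiza libraries. The SD of the log2 ratio between replicates, on edgeR's moderated log2 CPM, was 0.354 in mycelium and 0.933 in ectomycorrhiza. As a check for a library deposited more than once, chi-square per degree of freedom, which grows with depth, was 72 between the mycelium libraries and 40.2 between the ectomycorrhiza libraries, so each library was counted as its own sample.

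The series asks which fungal genes change expression in greenhouse ectomycorrhizas relative to the free-living mycelium. The groups differ at once in the presence of pine, in growth medium and in growth site. Growth time may differ too, since the mycelium was 6 days old and the age of the ectomycorrhizas at harvest is not given here. The calls below therefore cannot be assigned to the symbiosis alone. Of 11471 gene models tested, 5944 (51.8%) changed: 2791 were higher in ectomycorrhiza and 3153 were lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, n = 2 per group). The median log2 fold change was 1.80 among the higher and -1.94 among the lower gene models, or -1.84 with models at 0 reads in ectomycorrhiza set to their bound. All 5944 had both libraries of one group above both of the other, which 80.2% of all tested gene models also showed against 33.3% by chance. Of the tested models with mostly shared reads, 32 were among the calls.

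The balance of higher and lower gene models depended on how the libraries were scaled. Higher gene models made up 47.0% of the calls with TMM scaling, 50.8% with RLE (3011 higher, 2915 lower), 32.4% with upper-quartile scaling (2101 higher, 4377 lower) and 18.2% with total counts alone (1423 higher, 6405 lower). The median log2 fold change of all tested gene models moved from -0.20 with TMM to -0.11 with RLE, -0.59 with upper-quartile scaling and -1.15 with total counts. Directions below are relative to the TMM scaling. Of the 2791 higher gene models, 2101 kept their call with upper-quartile scaling and 1423 with total counts. Leaving out a mycelium library lowered the number of calls, and leaving out an ectomycorrhiza library raised it. The lone library was then assumed to vary like the other group.

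**Figure D1:**
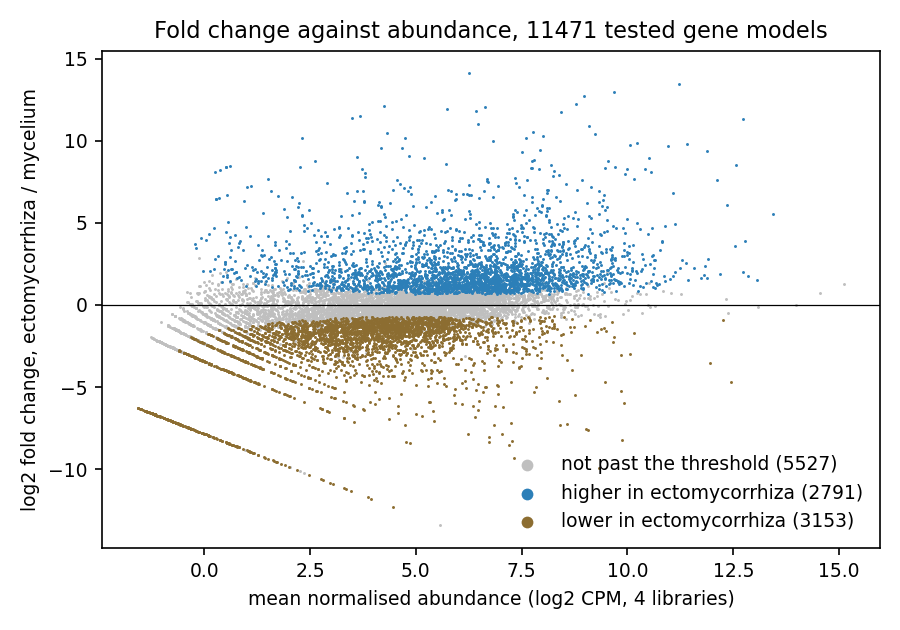
Log2 fold change (ectomycorrhiza over mycelium) against mean normalised abundance in log2 CPM, one point per tested gene model, coloured by the edgeR call. The plot shows 2791 higher and 3153 lower models; the straight lines of points at lower left are models with 0 or few reads in ectomycorrhiza, whose fitted fold depends on the prior count.

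Large changes were common in both directions. At least 5-fold changes past the threshold were found for 926 gene models higher in ectomycorrhiza and 1189 lower, or 1035 lower with models at 0 reads set to their bound. At least 100-fold changes, with such models at their bound, were found for 107 higher and 25 lower gene models, and by fitted folds for 112 and 200. The bound is weaker on the lower side, since 3 reads are 0.48 normalised CPM in ectomycorrhiza and 0.058 in mycelium. The 926 strongly higher models held 4.73% ± 0.014 of mycelium reads and 34.3% ± 1.55 of ectomycorrhiza reads (SD, n = 2), a set chosen on these same libraries. The 1189 strongly lower models held 10.8% ± 0.452 of mycelium reads and 0.425% ± 0.0315 of ectomycorrhiza reads (SD, n = 2). Which direction had more at least 5-fold changes depended on the test and scaling: DESeq2 gave 1001 higher and 968 lower, and edgeR with total-count scaling 539 higher and 2687 lower.

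The gene models at the ends of the ranking had 0 or few reads in one tissue and were well covered in the other. Their ranking rests on fitted folds, which depend on the prior count where a group is at 0 reads: with such models at their bound, 8 eligible gene models would stand ahead of 31169, 27 ahead of 23334, 46 ahead of 448535 and 0 ahead of 428551. Gene model 428551 (transcript of 871 bp) rose from 0.426 ± 0.006 to 4800 ± 3280 normalised CPM (SD, n = 2), a log2 fold change of 13.43 (SE 0.76, edgeR adjusted p = 0.00047), with 11 and 11 reads in mycelium and 23083 and 7420 in ectomycorrhiza. Gene model 31169 (456 bp) had 0 reads in both mycelium libraries and 718 and 250 reads in ectomycorrhiza, or 221 and 83.4 normalised CPM. Its ectomycorrhiza mean was at least 2620-fold higher (edgeR adjusted p = 0.0013), with 3810-fold in replicate 1 and 1440-fold in replicate 2 over the same 3-read limit. Gene model 23334 (1356 bp) had 1316 and 945 reads in mycelium, 43.8 ± 9.55 normalised CPM (SD, n = 2), and 0 in both ectomycorrhiza libraries. Its mean was at least 91-fold lower in ectomycorrhiza (edgeR adjusted p = 0.0011). Gene model 448535 (1825 bp) had 800 and 792 mycelium reads, 30.9 ± 0.22 normalised CPM (SD, n = 2), and 0 in ectomycorrhiza, at least 64.2-fold lower (edgeR adjusted p = 0.00082).

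Switch-like gene models were found on both sides. Among those past the threshold, 25 were under 1 normalised CPM in mycelium and at 100 or more in ectomycorrhiza, and they held 1.38% and 0.901% of the reads of the 2 ectomycorrhiza libraries. The reverse held for 6 gene models, with 0.159% and 0.251% of the mycelium reads. With all libraries thinned to 3967725 reads, 80 gene models had at least 10 reads in both mycelium libraries and 0 in both ectomycorrhiza libraries, and 15 showed the opposite; 79 of the 80 and all 15 were past the threshold in the full counts. In the full counts, 5 of the 80 had a read in ectomycorrhiza and 10 of the 15 had a read in mycelium. At 1 TMM-scaled size the numbers were 43 and 31, and in the unthinned counts 366 and 5. At the thinned depth, 12580 and 12506 gene models were detected in mycelium against 11527 and 11408 in ectomycorrhiza. Equal totals still left most models with less depth in ectomycorrhiza, where the TMM factors were 0.683 and 0.755 against 1.47 and 1.32 in mycelium. The detected numbers therefore do not measure how many genes each tissue expressed.

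The most abundant fungal transcripts were partly shared. Of the 5 most abundant gene models in each group, 3 were the same, and of the 100 most abundant, 44. The leading model was the same in both tissues, at 20990 ± 12274 normalised CPM in mycelium and 50405 ± 22232 in ectomycorrhiza (SD, n = 2), a log2 fold change of 1.26 that did not pass (edgeR adjusted p = 0.099). It took 1.80% (exact 95% binomial interval 1.798 to 1.811) and 3.92% (3.909 to 3.926) of the mycelium reads, and 4.52% (4.498 to 4.536) and 2.62% (2.603 to 2.635) of the ectomycorrhiza reads. The third most abundant in ectomycorrhiza went from 468 ± 39 to 21597 ± 4884 normalised CPM (SD, n = 2; log2 fold change 5.53, edgeR adjusted p = 0.00047), and the fifth had a log2 fold change of 11.32 (edgeR adjusted p = 0.00032). The fourth most abundant in mycelium fell from 10719 ± 2217 to 413 ± 52 normalised CPM (SD, n = 2; log2 fold change -4.70, edgeR adjusted p = 0.00054). Of the 100 most abundant in ectomycorrhiza, 88 were higher than in mycelium, 1 was lower and 11 did not pass, in a list picked by the ectomycorrhiza values themselves. With total-count scaling 71 of them were higher and 2 lower. Of the 100 most abundant in mycelium, 35 were higher in ectomycorrhiza, 32 lower and 33 did not pass, and with total-count scaling 15 were higher and 47 lower.

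By read counts, the ectomycorrhiza libraries were concentrated on fewer gene models. The number holding 50% of the reads was 747 and 550 in the mycelium libraries and 260 and 309 in the ectomycorrhiza libraries. The 100 most abundant held 27.98% ± 4.32 of mycelium reads and 35.2% ± 2.05 of ectomycorrhiza reads (SD, n = 2), while the 10 most abundant held 14.3% ± 4.46 and 13.95% ± 1.74, which overlapped between the groups. By RPKM, which divides by transcript length, the 100 most abundant held 33.0% and 41.4% in mycelium and 44.7% and 40.3% in ectomycorrhiza, so the groups overlapped, and 405 and 225 against 158 and 212 gene models held 50% of the summed values.

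**Figure D2:**
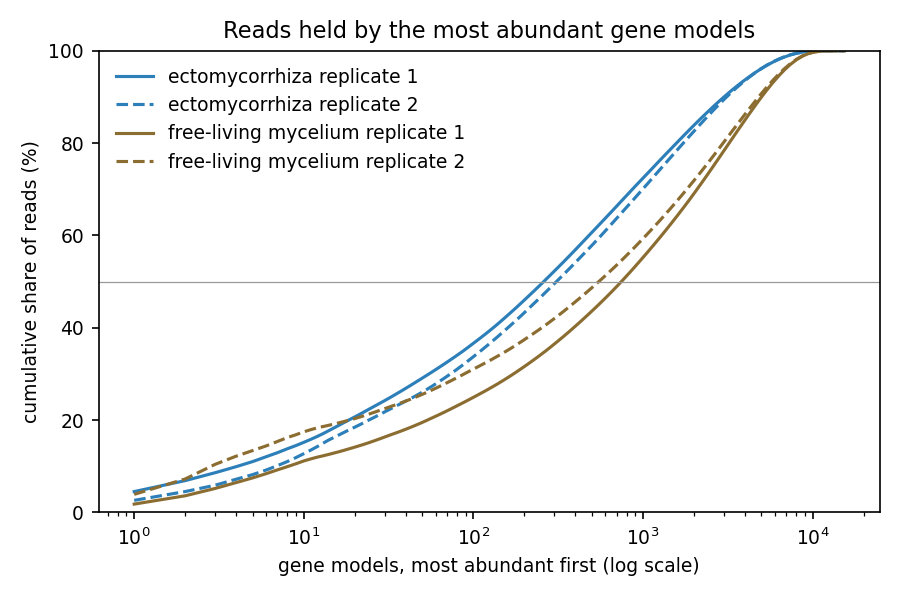
Cumulative share of reads (%) against the number of gene models, most abundant first, on a log axis, one line per library. The 50% line is crossed at 260 and 309 gene models in ectomycorrhiza and at 747 and 550 in mycelium.

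The relation between abundance and direction depended on which libraries set the ranking. Ranked by abundance in mycelium, the highest decile held 391 higher and 265 lower gene models, with a median log2 fold change of 0.22. The second lowest held 200 higher and 404 lower, with a median of -0.93, and the lowest 307 higher and 238 lower, with a median of -0.69. Across gene models, which are not independent replicates, log2 fold change had a Spearman rho of 0.154 with mycelium abundance, the denominator of the fold. With abundance taken from mycelium replicate 1 and the fold over replicate 2, rho was 0.165. Ranked by the mean of the 4 libraries, which holds the ectomycorrhiza value itself, the highest decile held 752 higher and 110 lower gene models, the lowest 96 higher and 357 lower, and rho was 0.465. Ranked by abundance in ectomycorrhiza alone, the highest decile held 896 higher and 20 lower gene models, the lowest 0 higher and 713 lower, and rho was 0.702. The filter partly set the lowest decile of each single-group ranking. A model with few reads in one group was tested only if it had enough reads in the other. Under total-count scaling the medians of the highest and lowest deciles of the mean of the 4 libraries were 0.51 and -2.42.

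**Figure D3:**
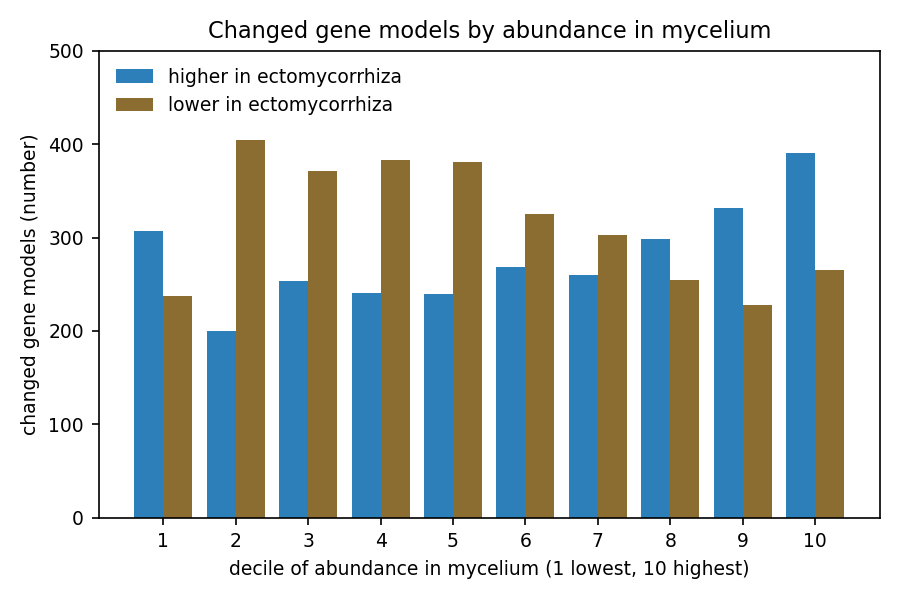
Number of gene models past the threshold, higher (blue) or lower (brown) in ectomycorrhiza with TMM scaling, by decile of mean abundance in the 2 mycelium libraries. Lower models outnumber higher ones in the second decile (404 against 200). Higher models outnumber lower ones in the highest decile (391 against 265) and in the lowest (307 against 238). The filter partly set the lowest decile, since models with few mycelium reads were tested only with enough ectomycorrhiza reads.

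Short transcripts were more often lower in ectomycorrhiza, and the ectomycorrhiza libraries also differed from each other along transcript length. Among 1103 tested gene models under 600 bp, 160 were higher and 398 lower, with a median log2 fold change of -1.06. Among 1655 models of at least 1800 and under 2400 bp, 514 were higher and 372 lower, with a median of 0.13. With a smooth length trend taken out of each library these became 259 higher and 311 lower under 600 bp (median -0.49) and 493 higher and 562 lower at 1800 to under 2400 bp (median -0.12). The class of 2400 bp or more went from 365 higher and 310 lower (median 0.10) to 407 higher and 562 lower (median -0.13), and after the correction lower models outnumbered higher ones in all 6 classes. The correction also removes a smooth length difference between the groups themselves. The corrected counts therefore cannot tell a library bias from a difference between the tissues. Between the ectomycorrhiza libraries the median log2 ratio of replicate 1 over replicate 2 was 0.72 under 600 bp and -0.73 at 2400 bp or more, against -0.06 and 0.14 between the mycelium libraries. For transcripts of 2400 bp or more the direction depended on the library, with a median log2 ratio over mycelium of -0.38 in replicate 1 and 0.41 in replicate 2. With total-count scaling all 6 length classes had negative medians, from -2.02 under 600 bp to -0.84 at 2400 bp or more.

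**Figure D4:**
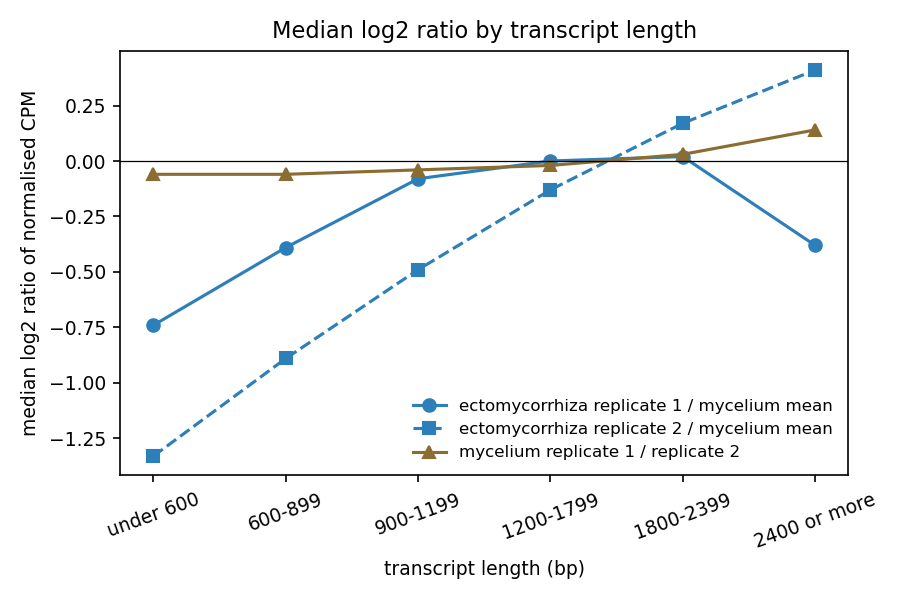
Median log2 ratio of normalised CPM (vertical axis) by class of transcript length in bp (horizontal axis), for each ectomycorrhiza library over the mycelium mean (blue) and for mycelium replicate 1 over replicate 2 (brown). Both ectomycorrhiza libraries lie below 0 under 600 bp (-0.74 and -1.33), and they part at 2400 bp or more (-0.38 and 0.41).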

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

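Thinning, the length correction, the crossed pairing, RPKM for the number of gene models holding 50% of the reads and deciles of abundance ranked by each group alone were chosen after the data were seen. The 4 named gene models kept their direction in all 64 alternative values. Log2 fold changes were 7.75 to 14.98 for the 2 higher and -12.64 to -4.62 for the 2 lower. The largest adjusted p was 0.0026, for 31169 with edgeR and no filter. The models were picked as extremes of these same counts, so that outcome was largely fixed beforehand. For the 3 at 0 reads in one group, the fitted folds depend on prior counts or pseudocounts. Total counts alone gave 1423 higher and 6405 lower gene models, and 539 higher and 2687 lower among 3226 changed at least 5-fold; limma on log2(RPKM + 1), which has the same scaling, gave 1401 higher and 6545 lower, with 463 higher at least 5-fold. Leaving out 1 library gave 3832 to 7539 changed gene models, 1690 to 3566 higher and 2142 to 4074 lower. The lowest counts came without a mycelium library, 3832 without replicate 1 and 3912 without replicate 2, and the highest without an ectomycorrhiza library, 7539 and 7461; the lone library was then assumed to vary like the other group. At least 5-fold, the range was 1964 to 2250 gene models, 846 to 986 higher and 1102 to 1394 lower. The total counts of changed, higher and lower gene models stayed within 1.5 times the reported ones under RLE, upper-quartile scaling, DESeq2 (5646 changed), limma-voom (6022), no filter (5643), the strict filter (5554), unique gene reads (5924), thinning (5569) and the length correction (7027). Within length classes the length correction moved 3 counts by more than 1.5 times, from 160 to 259 higher under 600 bp, from 372 to 562 lower at 1800 to under 2400 bp and from 310 to 562 lower at 2400 bp or more. The replicate numbers pair nothing that the labels name, and same-numbered libraries deviated with r = -0.213 across gene models; with the replicate block 5222 gene models changed, and with the numbers crossed 6566. By RPKM the 100 most abundant gene models held 33.0% and 41.4% in mycelium and 44.7% and 40.3% in ectomycorrhiza, so the groups overlapped, and 405 and 225 gene models in mycelium against 158 and 212 in ectomycorrhiza held 50%. Ranked by mycelium abundance instead of the mean of the 4 libraries, the highest decile fell from 752 to 391 higher and the lowest rose from 96 to 307 higher. The filter partly set that lowest decile, since models with few mycelium reads were tested only with enough ectomycorrhiza reads. The pseudocounts and the quantile normalization planned for normalised values were not run because counts were deposited, and the gene lists could not be built. Depth limits the lower side: 215 called gene models had 0 reads in both ectomycorrhiza libraries, and their folds are bounds.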

Other observations

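Of the 5 most abundant gene models in mycelium, 4 were 2.41, 2.33, 2.74 and 2.84 times higher in mycelium replicate 2 than in replicate 1 in normalised CPM, while the other was at 0.745. In ectomycorrhiza, replicate 1 was above replicate 2 for all 7 gene models among the 5 most abundant of either group, by 1.2 to 1.91 times. The 4 have transcripts of 450 to 821 bp, and the median log2 ratio of ectomycorrhiza replicate 1 over replicate 2 was 0.72 for all models under 600 bp and 0.52 at 600 to under 900 bp, so that shift is not particular to the 4; between the mycelium libraries the median of replicate 1 over replicate 2 was -0.06 in both classes. None of the 4 passed the threshold between the tissues.

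The groupings and patterns below were found in these data. Of the tests, the length relation between the ectomycorrhiza libraries and the thinned concentration were chosen after the result was seen, and the others had their outcomes stated first.

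Fold change rose with transcript length (Spearman rho = 0.179 across 11471 gene models). A length bias that differs between single libraries is one candidate explanation: the log2 ratio of the 2 ectomycorrhiza libraries, which belong to one group, fell with length at rho = -0.498, and the relation to mycelium was rho = 0.0478 with replicate 1 and 0.285 with replicate 2. Whether the lower abundance of short transcripts may also account for it stays open. Within deciles of mean abundance, which holds the fold change itself, the median rho was -0.0143, with 2 of 10 above 0. Within deciles of mycelium abundance, a ranking added later, the median rho was 0.112, with 10 of 10 above 0. Mycelium abundance is the denominator of the fold, so that ranking is not independent of it either. After a smooth length trend was taken out, an alternative also chosen afterwards, 2711 of the 2791 higher and 3010 of the 3153 lower gene models kept their call. A biological difference between short and long transcripts stays open and was not tested.

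The ectomycorrhiza libraries scattered more than the mycelium libraries, with an SD of log2 ratios of 0.910 against 0.381 when 0.5 reads were added to each count, as in the tests here, where the report uses moderated log2 CPM. At equal totals, lower depth does not account for all of it. Mycelium libraries thinned to the ectomycorrhiza totals reached an SD of 0.486, 53.4% of the ectomycorrhiza value (bootstrap interval over gene models 51.4 to 55.3). Equal totals do not give equal reads per model, since the ectomycorrhiza reads were concentrated on fewer models. Among models above median abundance the SD was 0.712 in ectomycorrhiza and 0.343 in thinned mycelium. The difference along transcript length carried 24.1% of the variance, and without it the ectomycorrhiza SD was still 163% of the thinned mycelium SD (157 to 170). Both intervals resample gene models, and each SD rests on the same 2 libraries of its group. They therefore do not cover how the SDs would vary with other libraries. Differences between plants or pots, in the stage of the root tips or in reads from pine or soil organisms stay open and were not tested, since the labels name no plant and no host reads were used here.

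Fewer gene models held 50% of the ectomycorrhiza reads; by RPKM the gap narrowed to 225 in the lower mycelium library against 212 in the higher ectomycorrhiza library. At one depth the lower mycelium library still needed 551 gene models against 309 in the higher ectomycorrhiza library, without the 10 most abundant models 956 against 448, and with the length trend taken out 612 against 274. Random thinning keeps the expected share of each model, so the value at one depth (550 before thinning) was largely fixed beforehand and is no test of depth. The 10 most abundant models held 14.3% of mycelium and 13.95% of ectomycorrhiza reads, so their removal could hardly close the gap either. Those similar shares and the length correction argue against a few dominant transcripts and the measured length trend as the whole cause of the pattern in read counts. Dividing by transcript length took away most of the gap to mycelium replicate 2. By RPKM the 10 most abundant models held 26.6% of that library, against 16.6% in mycelium replicate 1 and 23.3% and 18.4% in ectomycorrhiza. The values above without the 10 most abundant models are by read counts. A part tied to the length of the abundant transcripts therefore stays open. A biological difference between the tissues and reads of other organisms assigned to fungal models also stay open and were not tested.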
